A study of Homo sapiens with 43 samples.

How the data were processed

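Bulk RNA sequencing of 11 human pluripotent stem cell lines was used. Per the labels, polyadenylated RNA was made into directional libraries from samples whose RNA integrity number exceeded a stated minimum, and the libraries of a line are called biological replicates. The 43 libraries fell into 3 deposited tables. The cell line table held 22 untreated libraries, 2 for each of the 11 lines, and 8 libraries of cells given a chromatin restoration treatment, abbreviated CHR in the labels, from hehd1, burb1, fiaj1 and sojd3. The organoid table held 11 libraries, 1 organoid library per line at day 20. A further table held 2 libraries of CHR-treated sojd3 cells, at passages 37 and 38. The design text calls 5 lines competent (deyz2, H1, H9, hehd1 and kolf2) and 6 noncompetent (burb1, cuhk2, feec2, fiaj1, HUES8 and sojd3), and the groups were taken from it and not from the data. The labels of the HUES8 libraries name the cell line HUES8-iCas9, and it is called HUES8 here as in the design text. The labels give no batch, date or run for any library.

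The deposited values are TPM, transcript abundances scaled to the same total in each library, for 60675 genes, and per the labels they are merged gene-level values from salmon. Each column held values that are not whole and that add up to the same total. Trim Galore, STAR 2.7.9a, SAMtools 1.21, DESeq2 and the genome build GRCh38 are named in the submitters' processing notes, without their roles. The annotation release and salmon's version are not given in the sources used here. TPM divides each library by its own total, so an abundant transcript in 1 library lowers the others there, and it keeps no depth. Depth per library was therefore unknown, and the precision of a value rests on the spread between libraries alone. The 3 tables were normalised separately, so tests were run only within a table. Use of strand in the authors' counting is not stated, and reads of overlapping, antisense or near-identical genes may be split between them.

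Gene identifiers were matched to GENCODE release 29 on GRCh38 for positions, and 58444 of the 60675 had an entry. XIST, TSIX and Y-linked genes (516 per table) were left out of every test. Values were analysed as log2(TPM + 1). A gene was kept in a comparison if it reached 1 TPM in at least 2 of its libraries. Fold changes are differences on the log2(TPM + 1) scale, which understate the change of genes near or below 1 TPM.

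Comparisons of competence took the line as the replicate: the 2 untreated libraries of a line were averaged on the log2 scale, and lines were compared with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3. The change with CHR was fitted in 2 ways. Across the 4 treated lines, line means were compared with the line as a covariate. For the 3 noncompetent treated lines, for hehd1 and for the difference between them, contrasts were taken from a fit of all 30 libraries with a mean for each line and treatment. The spread in that fit is between the 2 libraries of a line and treatment, so its p-values speak of these cultures and not of further lines. Replicate libraries are not traced to separate thaws or wells in the labels, and p-values measure only the spread between these samples, part of which may be technical. All tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Adjusted p-values of genes are from limma throughout.

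The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except for the alternatives and tests named in the text as added or chosen afterwards. There were 34 gene lists, of cell types, pluripotent states, signalling targets and stress responses. A list was tested where at least 5 of its members were kept, with camera (preset correlation 0.01), camera with an estimated correlation, and fry. camera asks whether a list moved relative to other genes, and fry whether its members moved, on balance, one way. List members were also adjusted over the list alone. Named genes are up to 4 members of a list with the smallest adjusted p and its member of largest change, the 8 genes outside the lists with the smallest adjusted p in each direction (at least 1 log2 unit, a mean of at least 5 TPM in a group, and no overlap between lines or the same direction in each treated line), and a fixed set of pluripotency and neural regulators whatever their result. If no gene passed, the 4 with the smallest p in each direction were taken.

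For the shift of competence genes with CHR, lists of 100 genes per direction came from the 7 lines without CHR libraries, and the change was read in the treated lines, so that no library entered both. The median change of a list was ranked among 10000 random lists matched on mean expression in 50 bins. Other splits of the samples were counted up to 100 per comparison. Each test was checked on simulated data made from these values, with 200 genes changed. In the comparison of untreated lines (17726 genes) 64.2% of changes of 1 log2 unit and 97% of changes of 2 were recovered, with 5 false calls. In the noncompetent lines with CHR (18096 genes) the shares were 80.6% and 98.5%, with 9 false calls, in hehd1 (18096 genes) 29.9% and 87.9%, with 6, and in the organoids (20543 genes) 20.9% and 65.2%, with 2.

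Alternatives covered a pseudocount of 0.1, no filter, a mean of at least 5 TPM, quantile and median-of-ratios scaling, robust variance, each line or library left out, other units of replication and the origin of the lines. Added after seeing the data were fits without mitochondrial genes, without the 2 libraries that stand apart, and without 3 organoids with retained pluripotency RNA. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots. The tables hold RNA levels alone, and the competence assay itself was not analysed here. Results of some genes are not reported here.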

Results

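RNA levels were measured in 11 human pluripotent stem cell lines, of which H1, H9 and HUES8 (HUES8-iCas9 in the labels) are embryonic and the other 8 were made by reprogramming. The design text calls 5 lines competent and 6 noncompetent for differentiation. Each line had 2 untreated libraries. CHR, a chromatin restoration treatment, had 2 libraries in each of hehd1 (competent), burb1, fiaj1 and sojd3 (noncompetent). Each line also had 1 organoid library at day 20, and sojd3 had 1 CHR library at passage 37 and 1 at passage 38. The organoid type is not given in the sources used here. Untreated lines were grown in E8 medium on vitronectin and CHR lines in StemFlex with 3 µM IWP2, an inhibitor of WNT secretion, on laminin, so treatment and culture changed together in each CHR comparison. Depth per library was unknown, since TPM keeps none. In the cell line table mitochondrial genes took between 1.96% and 13.6% of the TPM, with the highest shares in H9 untreated replicate 2 (13.6%) and sojd3 CHR replicate 2 (12.1%). The 3 tables were normalised separately, and limma, camera and fry were run only within a table. Levels are TPM means ± SD, and changes are differences in log2(TPM + 1), which understate the change of low genes.

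The design asks whether untreated competent and noncompetent lines differ before differentiation. Noncompetent lines held far more RNA of SP8, a zinc finger factor of the anterior neural border, of GBX2, which patterns the midbrain-hindbrain border, and of ZIC1, an early neural plate factor. UTF1, a chromatin-bound factor of pluripotent cells, and PDGFA, a growth factor, were also higher there. Competent lines held more of the contractile genes MYL9, TNNT2 and ACTC1 and of the mesenchymal genes TAGLN and COL1A1. The core factors POU5F1, SOX2 and NANOG were not called. GBX2 (ENSG00000168505, GRCh38 chromosome 2, 236165236 to 236168369) was at 0.964 ± 0.583 TPM in the 5 competent lines and 29.6 ± 15.5 in the 6 noncompetent lines, a log2 difference of -3.83 ± 0.32 (SE, adjusted p = 0.000119). SP8 (ENSG00000164651, chromosome 7, 20782283 to 20786886) was at 3.23 ± 1.5 against 65.3 ± 24.3 TPM (-3.89 ± 0.35, adjusted p = 0.000181). UTF1 (ENSG00000171794, chromosome 10, 133230274 to 133231558) was at 15.1 ± 3.86 against 162.7 ± 56.7 TPM (-3.29 ± 0.30, adjusted p = 0.000181). ZIC1 (ENSG00000152977, chromosome 3, 147393422 to 147510293) was at 0.777 ± 0.274 against 71.2 ± 45.4 TPM (-4.71 ± 0.73, adjusted p = 0.00411). MYL9 (ENSG00000101335, chromosome 20, 36541484 to 36551447) went the other way, at 148.8 ± 23.9 against 36.2 ± 13.9 TPM (2.06 ± 0.23, adjusted p = 0.000808). For each of these 5 genes no competent line overlapped a noncompetent line. The gap was narrow for ZIC1, at 2.87 TPM in noncompetent cuhk2 and 1.13 in competent H1. SP8 (17.5 TPM) and UTF1 (52.9) were also lowest in cuhk2 among the noncompetent lines, while GBX2 was lowest in burb1 (10.4).

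**Figure D1:**
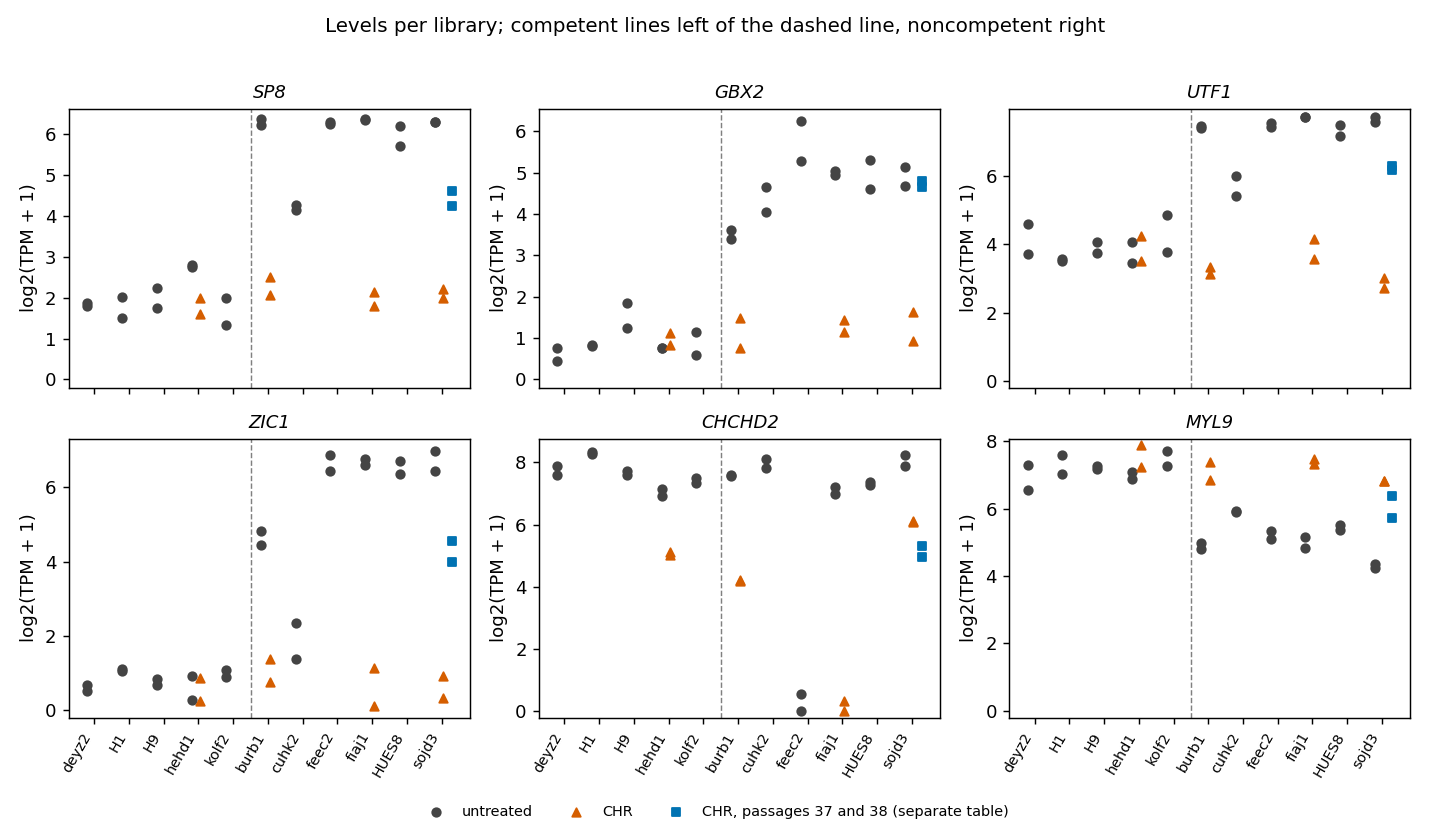
Levels of SP8, GBX2, UTF1, ZIC1, CHCHD2 and MYL9 as log2(TPM + 1) in each library of the 11 lines, with competent lines left of the dashed line. Grey circles are untreated libraries, orange triangles CHR libraries and blue squares the CHR libraries of passages 37 and 38 from a table normalised separately. SP8 mean TPM went from 77.8 to 3.92 in burb1, from 80.7 to 2.96 in fiaj1 and from 77.7 to 3.31 in sojd3.

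In limma, 636 of 17726 genes differed between the untreated groups, 321 higher and 315 lower in competent lines. A change of at least 1 log2 unit was seen in 145 of the higher and 157 of the lower genes. Outside the lists, the smallest adjusted p-values among genes lower in competent lines were those of ISLR2 (-2.34), PDGFA (-2.21), BAHCC1 (-3.14), CNTFR (-2.81), B3GNT7 (-1.20), VENTX (-2.46), MLLT6 (-1.97) and SLC16A12 (-1.86). Those higher were NAP1L3 (1.31), MYL9, ECSCR (1.60), FAM71F1 (1.44), LHFPL6 (1.83), TNFRSF11A (1.39), CLC (2.63) and DENND2B (1.03). The adjusted p of these genes ran up to 0.0019 (DENND2B). Among the regulators named whatever their result, OTX2 was at 1.23 ± 0.33 (adjusted p = 0.0581), POU5F1 at -0.40 ± 0.12 (0.0751), ZIC2 at -0.91 ± 0.28 (0.0935), NANOG at -1.13 ± 0.35 (0.099), PAX6 at -1.003 ± 0.36 (0.145), DNMT3B at 0.29 ± 0.21 (0.49) and SOX2 at 0.06 ± 0.24 (0.928).

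Of the midbrain and diencephalon list, 12 members were measured: 3 were lower in competent lines (GBX2, PAX5 at -1.78 and IRX1 at -2.92), 0 higher and 9 not called, and adjusted over the list alone 8 were lower and 1 higher. The camera test placed the list lower (adjusted p = 0.00257), and with an estimated correlation the adjusted p = 0.385. Of the posterior epiblast and primitive streak list, WNT5B (-0.88) and FGF17 (-0.78) were lower among 19 measured, 17 were not called, and 7 were lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00622, and adjusted p = 0.385 with an estimated correlation). The anterior epiblast and neural ectoderm list was split: of 21 measured, SP8, ZIC1 and SIX3 (-2.64) were lower, while FABP7 (1.91), a radial glia fatty acid binder, and HESX1 (0.94), a forebrain repressor, were higher, and 16 were not called. Adjusted over the list alone, 9 were lower and 4 higher (camera adjusted p = 0.0463, and adjusted p = 0.543 with an estimated correlation). Of 9 telencephalon genes measured 3 were lower, SP8, which this list shares, and GAD2 (-1.05) among them, 6 were not called, and 4 were lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0267, and adjusted p = 0.385 with an estimated correlation). Of 16 neural progenitor genes, DLL1 (-2.27) was lower, FABP7 higher and 14 not called, and adjusted over the list alone 2 were lower and 1 higher (camera adjusted p = 0.0334, and adjusted p = 0.385 with an estimated correlation).

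Among FGF and ERK targets, CCND1 (-1.46), a G1 cyclin, and the feedback inhibitors SPRY1 (-0.82) and SPRY2 (-0.85) were lower in competent lines, and 16 of 19 were not called. Adjusted over the list alone 8 were lower and 0 higher (camera adjusted p = 0.00622, and adjusted p = 0.385 with an estimated correlation). Of 14 naive pluripotency genes TFAP2C (-1.38) was lower and 13 were not called, with 1 lower adjusted over the list alone (camera adjusted p = 0.025, and adjusted p = 0.385 with an estimated correlation). Of 11 muscle genes TNNT2 (2.02), ACTC1 (2.02) and TNNC1 (1.46), parts of the contractile filament, were higher and 8 were not called, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00257, and adjusted p = 0.385 with an estimated correlation). Of 14 fibroblast and mesenchyme genes TAGLN (1.75), COL1A1 (2.03), PDGFRB (1.11) and S100A4 (1.37) were higher and 10 were not called, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.025, and adjusted p = 0.385 with an estimated correlation). Genes of chromosome band 20q11.21, a region often gained in cultured pluripotent cells, were shifted up in camera (adjusted p = 0.00853, and adjusted p = 0.419 with an estimated correlation), with HM13 (0.64) the called member of 18, both over all genes and adjusted over the list alone. UTF1 was the called member of 20 core pluripotency genes, and adjusted over the list alone 5 were lower and 2 higher (camera adjusted p = 0.489), with a median of 0.07 against a mean of -0.24. In all, 10 lists passed camera, 0 with an estimated correlation (8 of these 10 at an adjusted p of 0.385) and 5 passed fry. The count of genes rested in part on single lines: it was 1040 without cuhk2, 340 without deyz2, 354 without feec2, 350 without fiaj1, 345 without H1, 394 without kolf2 and 402 without sojd3.

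The 4 treated lines were compared before and after CHR to ask what the treatment does to these cells. Across them, PKIB, an inhibitor of protein kinase A, BEX1 and SPIB rose, and STC1, a secreted glycoprotein, SALL3 and CRABP1, a retinoic acid binder, fell. In limma on line means 21 of 17222 genes were called, 11 higher and 10 lower, with adjusted p between 0.0428 and the threshold of 0.05. PKIB changed by 1.23 ± 0.12, BEX1 by 1.42 ± 0.14, SPIB by 1.57 ± 0.17, MYL7 by 2.01 ± 0.23 and NTS by 1.55 ± 0.19, and STC1 by -1.09 ± 0.11, SALL3 by -1.52 ± 0.16, CRABP1 by -1.17 ± 0.14 and MAGI2 by -1.22 ± 0.15. Of 12 naive pluripotency genes none passed over all genes in limma, and 6 were lower adjusted over the list alone (camera adjusted p = 1.51e-05, and adjusted p = 0.641 with an estimated correlation). The count was 0 under quantile or median-of-ratios scaling, 627 without hehd1, 27 without sojd3, 1 without fiaj1 and 0 without burb1. At an unadjusted p under 0.05 there were 3229 genes.

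In the 3 treated noncompetent lines SP8, ZIC1, GBX2 and UTF1 fell with CHR in each line, as did the T-box factor TBX1 and CNTFR, a cytokine receptor subunit. MYL9, TNNT2, ACTC1 and TAGLN rose over the 3 lines, though TNNT2 and ACTC1 missed the threshold in burb1 alone (limma adjusted p = 0.0711 and 0.14). CHCHD2, a mitochondrial protein and transcription cofactor, had the smallest adjusted p, and the metallothioneins MT1F and MT1G, which bind metals, also fell. SP8 was at 78.7 ± 1.70 TPM before and 3.40 ± 0.485 after CHR (SD over 3 lines), a change of -4.20 ± 0.14 (SE, adjusted p = 3.81e-14). ZIC1 changed by -5.23 ± 0.21 (adjusted p = 4.76e-13), UTF1 by -4.28 ± 0.19 (3.22e-12) and GBX2 by -3.24 ± 0.20 (5.75e-10). CHCHD2 (ENSG00000106153, chromosome 7, 56101569 to 56106576) went from 190.6 to 17.5 TPM in burb1, from 135.3 to 0.128 in fiaj1 and from 266.9 to 67.1 in sojd3 (-4.09 ± 0.10, adjusted p = 3.07e-16). MT1F changed by -5.63 ± 0.22 and MT1G by -5.87 ± 0.28, with adjusted p of 4.36e-13 and 6.51e-12, though reads of these near-identical paralogs may have been shared between them. MYL9 rose by 2.39 ± 0.14 (adjusted p = 4.1e-10).

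In limma 3094 of 18096 genes changed in these lines, 1562 up and 1532 down. A change of at least 1 log2 unit was seen in 180 that rose and 401 that fell. The count was 1150 in burb1 alone, 1062 in fiaj1 and 898 in sojd3. Between burb1 and fiaj1 246 falling and 108 rising genes were shared, where independent lists of that size would share 22.8 and 11.8. Between fiaj1 and sojd3 265 falling and 149 rising genes were shared, against 15.14 and 11.24, and between burb1 and sojd3 199 and 79, against 17.01 and 11.56. Across all genes tested the changes of burb1 and sojd3 had r = 0.294, those of burb1 and fiaj1 0.464 and those of fiaj1 and sojd3 0.459, and genes are not independent replicates. With the competent line hehd1, r was 0.286 for burb1, 0.199 for fiaj1 and -0.00156 for sojd3. Between burb1 and fiaj1 18 genes rose in the first and fell in the second, and 2 did the reverse. Other leading genes that fell were CNTFR (-3.99), BAHCC1 (-3.52), FOXC1 (-2.10, at 0.118 TPM before and 0.104 after CHR in burb1) and PDGFA (-2.00), and those that rose were GPRC5D-AS1 (3.14), TRIM61 (2.15), LINC02864 (2.7, at 0.0213 TPM before and 0.0868 after CHR in fiaj1), HNMT (1.78), PKIB (1.32), BEX1 (1.52) and LINC01090 (2.18). Of the core factors, NANOG changed by -1.24 ± 0.28 (adjusted p = 0.00347), POU5F1 by -0.39 ± 0.10 (0.00929) and SOX2 by -0.42 ± 0.12 (0.0237). ZIC2 changed by -0.46 ± 0.12 (0.0129) and PAX6 by -0.84 ± 0.26 (0.0297), while OTX2 at 0.89 ± 0.34 (0.077) and DNMT3B at -0.19 ± 0.20 (0.585) were not called. With line means paired within the 3 lines, 627 genes passed, and 53 of the 114 named genes checked lost the call.

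Naive pluripotency genes fell with CHR: of 14 measured 9 fell, DPPA3 (-2.10), FGF4 (-1.98), TFAP2C (-1.86) and DPPA5 (-2.26) among them, 0 rose and 5 were not called, with 9 falling adjusted over the list alone (camera adjusted p = 1.61e-09, and adjusted p = 0.00997 with an estimated correlation). The midbrain and diencephalon list fell, with 8 of 12 down (GBX2, LMX1B at -1.59, PAX5 at -1.90 and PAX7 at -1.78), 1 up and 3 not called, and 8 down and 2 up adjusted over the list alone (camera adjusted p = 1.03e-06, and adjusted p = 0.00997 with an estimated correlation). The posterior epiblast and primitive streak list fell, with WNT5A (-1.38), GSC (-1.16) and FGF17 (-1.05) among 8 of 19 down and CER1 (1.24), a NODAL and WNT antagonist, the 1 up, the same counts adjusted over the list alone (camera adjusted p = 0.000899, and adjusted p = 0.0263 with an estimated correlation). Neuronal genes fell, 7 of 13, with TUBB3 (-1.33), INA (-1.04) and STMN2 (-1.76) down and RTN1 (0.74) up, and 8 down and 1 up adjusted over the list alone (camera adjusted p = 0.000899, and adjusted p = 0.0131 with an estimated correlation). Telencephalon genes fell, 5 of 9, with SP8 and GAD2 (-1.57) among those down and EMX1 (2.57) up, and 5 down and 2 up adjusted over the list alone (camera adjusted p = 0.00761, and adjusted p = 0.0401 with an estimated correlation).

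Of 21 anterior epiblast and neural ectoderm genes 10 fell, SOX1 (-2.08) among them, and 4 rose, POU3F1 (1.45) among them, with 11 down and 5 up adjusted over the list alone (camera adjusted p = 0.00384, and adjusted p = 0.407 with an estimated correlation). Of 20 core pluripotency genes 7 fell, including UTF1, GDF3 (-2.28) and FOXD3 (-0.86), and EPCAM (0.59) rose, with 8 down and 2 up adjusted over the list alone (camera adjusted p = 0.000899, and adjusted p = 0.407 with an estimated correlation). Of 11 muscle genes 6 rose, with TNNT2 (2.03), ACTC1 (2.18) and ACTA1 (1.61), and PAX7 fell, the same counts adjusted over the list alone (camera adjusted p = 0.0188, and adjusted p = 0.0606 with an estimated correlation). Of 14 mesenchyme genes 7 rose, with TAGLN (2.22), PDGFRB (1.55) and FBN1 (0.92), and 2 fell, with TWIST2 (-1.03), again alike adjusted over the list alone (camera adjusted p = 0.0327, and adjusted p = 0.407 with an estimated correlation). In all 13 lists passed camera, 5 with an estimated correlation and 16 passed fry.

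In hehd1, the competent line given CHR, PSMD5, a proteasome assembly chaperone, and the neighbours CRYZ and TYW3 rose from near 0, and CHCHD2 fell. SP8 (-0.98 ± 0.25, limma adjusted p = 0.139), GBX2 (0.22 ± 0.35, 0.963) and UTF1 (0.12 ± 0.33, 0.992) were low before treatment and were not called. PSMD5 (ENSG00000095261, chromosome 9, 120815496 to 120842984) went from 0.163 ± 0.0763 to 25.8 ± 2.19 TPM (n = 2 each), a change of 4.53 ± 0.17 (limma adjusted p = 5.07e-13). CRYZ (3.38 ± 0.15) and TYW3 (2.94 ± 0.16) overlap only at their ends on chromosome 1 (74705482 to 74733408 and 74733152 to 74766678). Only reads of that short stretch may not be separable. LINC02864 (4.73), C9orf64 (2.77), ECHDC3 (3.64), GDA (2.92), PCDHB5 (1.84), the imprinting regulator ZFP57 (1.68), the imprinted gene NNAT (1.58) and CAT (1.53), which encodes catalase, also rose, and CHCHD2 (-1.96 ± 0.18), RHOXF1-AS1 (-1.38), SPON1 (-1.25) and TOB1 (-1.07) fell. In all 62 of 18096 genes changed, 52 up and 10 down. Immediate early and dissociation stress genes shifted up as a list in camera (adjusted p = 4.1e-10, and adjusted p = 0.0594 with an estimated correlation): over all genes 0 of 17 passed limma, and 6 were up adjusted over the list alone. NODAL and activin targets, LEFTY1 (3.79 ± 1.09, adjusted p = 0.26) first in size among them, had 0 of 13 called and 4 up adjusted over the list alone (camera adjusted p = 0.000217, and adjusted p = 0.566 with an estimated correlation). At an unadjusted p under 0.05 there were 1345 genes, and the count was 36 without untreated replicate 1 and 39 without CHR replicate 1 or without untreated replicate 2.

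The difference between the responses was tested directly. PSMD5 (-4.39 ± 0.19), CRYZ (-3.10 ± 0.18), TYW3 (-2.76 ± 0.18), C9orf64 (-3.43 ± 0.26) and ECHDC3 (-3.80 ± 0.35), which rose in hehd1, changed in the lower direction in the noncompetent lines relative to hehd1. For C9orf64 and ECHDC3 the difference was larger than the rise in hehd1, so on average they did not rise in the noncompetent lines. For PSMD5, CRYZ and TYW3 the starting levels differed, being near 0 in untreated hehd1 alone. Before CHR, PSMD5 was at 26.95 TPM in burb1, 31.5 in fiaj1 and 24.79 in sojd3, and CRYZ at 69.79, 70.8 and 20.86. MT1F (-7.88 ± 0.44), MT1G (-8.13 ± 0.55), TBX1 (-3.82 ± 0.25), GBX2 (-3.46 ± 0.40) and POU5F1 (-0.81 ± 0.20, adjusted p = 0.0378) also changed in the lower direction relative to hehd1. MT1F went from 2.28 to 12.4 TPM in hehd1, against 153.5 to 2.18 over the noncompetent lines. TBX1 was at 0.0481 TPM and GBX2 at 0.681 in untreated hehd1, so neither could fall far there. In the untreated noncompetent lines the lowest levels were those of burb1, 6.60 TPM for TBX1 and 10.4 for GBX2. For such genes the test cannot tell a different response from a different starting level. MYL9 (1.80 ± 0.29), GPRC5D-AS1 (3.48 ± 0.26), CD74 (1.44 ± 0.22), S100A16 (1.85 ± 0.30), GALNT14 (1.69 ± 0.27), CHGA (2.68 ± 0.44), PCLAF (2.03 ± 0.34) and TCEAL7 (1.59 ± 0.27) changed in the higher direction. GPRC5D-AS1 was already at 11.25 TPM in untreated hehd1, against at most 0.213 (fiaj1) in these noncompetent lines before CHR. In limma 360 genes differed, 119 higher and 241 lower, with adjusted p for GBX2 of 2.77e-05 and for MYL9 of 0.000964. The midbrain and diencephalon list was lower, with 4 of 12 called and 7 adjusted over the list alone (camera adjusted p = 2.45e-08, and adjusted p = 0.00364 with an estimated correlation). The naive list was lower, with 5 of 14 called and 6 adjusted over the list alone (camera adjusted p = 4.78e-07, and adjusted p = 0.0187 with an estimated correlation). The count was 236 without hehd1 CHR replicate 1, 214 without hehd1 CHR replicate 2, 177 without hehd1 untreated replicate 1 and 212 without hehd1 untreated replicate 2.

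The series title calls the regional state reversible, which asks whether treated noncompetent lines still differ from competent ones. Before CHR, burb1, fiaj1 and sojd3 held more BAHCC1, TBX1, CNTFR, GBX2, IRX4 and OLIG3 RNA than the 5 competent lines, the last 2 being neural patterning factors, and less MYL9, CHGA, TIMP1 and BEX1. After CHR no gene passed. Untreated, 473 of 17300 genes differed in limma, 283 higher and 190 lower in these 3 lines, BAHCC1 by 3.62 ± 0.22 (adjusted p = 2.94e-05), IRX4 by 2.71 ± 0.19, CNTFR by 3.30 ± 0.25, TBX1 by 3.52 ± 0.28, OLIG3 by 3.67 ± 0.31, MYL9 by -2.46 ± 0.19 and CHGA by -1.95 ± 0.22. After CHR the limma count was 0 of 17110, with 941 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.394. The genes that the naming rule took, all of which missed the threshold, were GDA (2.48 ± 0.39), TCL1A (1.32 ± 0.39) and SNHG5 (1.33 ± 0.63) on the higher side and JAKMIP2-AS1 (-1.40 ± 0.24), TRIML2 (-1.19 ± 0.22), PIM2 (-1.0 ± 0.19) and EMP3 (-1.21 ± 0.23) on the lower. In a simulation of this comparison over 17110 genes, 53.7% of changes of 1 log2 unit and 90.9% of changes of 2 were recovered, so a smaller difference may have been missed. Large differences that vary between lines can be missed too, so a count of 0 does not show a full match. CHCHD2 was not called, at 17.5 TPM in burb1, 0.128 in fiaj1 and 67.1 in sojd3 after CHR. In the untreated competent lines it was between 130.1 (hehd1) and 315.9 (H1). GBX2 was at 1.39 TPM in the treated lines against 0.964 in the competent ones (0.31 ± 0.22, adjusted p = 0.925). Naive pluripotency genes were lower as a list in camera (adjusted p = 1.58e-05, and adjusted p = 0.499 with an estimated correlation), with 4 of 12 lower adjusted over the list alone, DPPA5 (-0.98) and DPPA3 (-1.20) among its members of smallest p, and BMP targets were higher (adjusted p = 0.0014, and adjusted p = 0.499 with an estimated correlation), with 2 of 9 higher adjusted over the list alone. Without sojd3 the count after CHR was 11. The count before CHR was 90 without fiaj1, 113 without sojd3, 231 without deyz2, 259 without H1, 263 without kolf2 and 722 without H9.

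The movement was also measured with lists that share no library with the CHR change: the 100 genes higher and the 100 lower in competent lines with the smallest p in limma of the 7 lines without CHR libraries, among genes that differ by at least 1 log2 unit. In burb1, fiaj1 and sojd3 together the higher list rose, with a median change of 0.88 and 92 of 100 genes up, and the lower list fell, with a median of -1.28 and 96 of 100 genes down. Random lists matched on expression had medians between -0.12 and 0.15 for the higher list and between -0.13 and 0.16 for the lower list, so both lists lay outside all 10000 draws. The lists themselves differed by medians of 1.39 and -1.39 between competent and noncompetent lines. In burb1 the medians were 0.53 and -0.92, in fiaj1 1.11 and -1.54, and in sojd3 0.89 and -1.46. In hehd1 they were -0.01 and -0.02, at percentiles 88.3 and 86.4 of the draws.

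**Figure D2:**
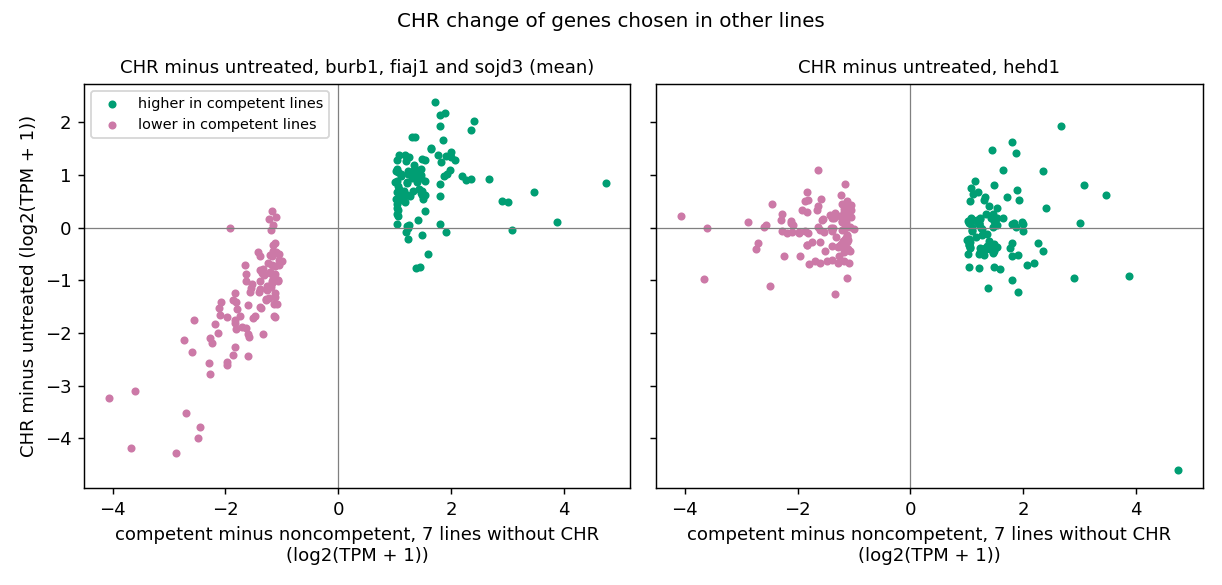
Each point is a gene of the 2 lists, with the log2 difference between competent and noncompetent lines among the 7 lines without CHR libraries on the horizontal axis and the log2 change from untreated to CHR on the vertical axis. The left panel takes the mean of burb1, fiaj1 and sojd3 (list medians 0.88 and -1.28) and the right panel hehd1 (-0.01 and -0.02).

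Organoids at day 20 were compared to ask what each group of lines had become. Competent lines gave organoids rich in forebrain genes: EMX2, FEZF2 and OTX1, regulators of the cortex, PAX6, which is needed for neural progenitors and the eye, and the WNT ligands WNT8B and WNT7B. Noncompetent lines gave organoids with collagens, POSTN, LAMB1 and S100A10, and several held endoderm RNA such as AFP and APOA1. EMX2 (ENSG00000170370, chromosome 10, 117542444 to 117549546) was at 563.1 ± 263.2 TPM in 5 competent organoids and 0.267 ± 0.166 in 6 noncompetent ones (8.63 ± 0.34, limma adjusted p = 1.66e-07). PAX6 (ENSG00000007372, chromosome 11, 31784779 to 31818062) was at 549.7 ± 192.9 against 5.86 ± 12.7 TPM (7.67 ± 0.76, adjusted p = 8.94e-05). COL1A1 was at 15.1 ± 1.82 against 1337 ± 1034 TPM (-5.55 ± 0.83, adjusted p = 0.00119).

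In limma 5154 of 20543 genes differed, 3766 higher and 1388 lower in competent organoids (73.1% higher). The median log2 difference of all genes was 0.22, and under median-of-ratios scaling the split was 48.9% higher of 3712 genes and under quantile normalization 60.8% of 4385, so changes of about that size depend on the scaling. Other leading genes were LHX5-AS1 (6.43), CACHD1 (3.11), WNT7B (6.48), PLCH1 (3.24), DMRT3 (5.85), ZBTB16 (3.66), EMX2OS (6.78) and FEZF1-AS1 (6.34) on the higher side. On the lower side were COL4A1 (-3.03), S100A10 (-6.53), OSTF1 (-2.75), OSBPL10 (-3.53), LAMB1 (-4.55), TMBIM1 (-4.45), MMP14 (-3.84) and TMC6 (-3.15). The adjusted p of these genes ran up to 3.66e-05 (TMC6). Of the fixed regulators OTX2 (4.85 ± 0.75), ZIC2 (3.59 ± 0.64) and SOX2 (3.93 ± 1.16) were higher, while POU5F1 (-3.85 ± 1.67, adjusted p = 0.103), NANOG (-2.26 ± 1.19, 0.168), TBXT (-0.93 ± 0.53, 0.196) and DNMT3B (-0.57 ± 0.76, 0.591) were not called. POU5F1 was at 1262 TPM in sojd3, 193.5 in fiaj1 and 26.3 in burb1 and at most 1.214 in the other lines.

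Of 24 anterior epiblast and neural ectoderm genes 20 were higher in competent organoids, with LHX5 (6.02), SOX3 (6.29) and FEZF1 (5.21), 1 was lower and 3 were not called, the same counts adjusted over the list alone (camera adjusted p = 1.58e-08, and adjusted p = 0.265 with an estimated correlation). Of 20 neural progenitor genes 17 were higher, HES5 (5.00) among them, 0 lower and 3 not called, with 18 higher adjusted over the list alone (camera adjusted p = 2.07e-09, and adjusted p = 0.265 with an estimated correlation). Of 18 telencephalon genes 10 were higher, FEZF2 (6.95) and OTX1 (6.47) among them, and 8 not called, with 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000388, and adjusted p = 0.4 with an estimated correlation). Of 18 choroid plexus and cortical hem genes 10 were higher, including WNT8B (7.29), LMX1A (4.29), WNT2B (3.90) and RSPO1 (4.45), and 2 lower, with 10 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0436, and adjusted p = 0.436 with an estimated correlation). Of 14 eye field genes 8 were higher, SIX3 (3.17) and LHX2 (4.16) among them, and 9 adjusted over the list alone (camera adjusted p = 0.0115, and adjusted p = 0.265 with an estimated correlation). Cell cycle genes were higher too, 12 of 23, with MCM2 (1.68) and TOP2A (1.24), and 21 higher and 1 lower adjusted over the list alone (camera adjusted p = 7.29e-05, and adjusted p = 0.441 with an estimated correlation); the called count was 5 under median-of-ratios scaling, none of them lower. Of 18 HOX and hindbrain genes 0 passed limma, over all genes or adjusted over the list alone, HOXD4 (1.28, adjusted p = 0.0803) among those of smallest p.

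Of 19 fibroblast and mesenchyme genes 11 were lower in competent organoids, with COL1A1, POSTN (-7.10), COL1A2 (-4.05) and COL3A1 (-6.39), 0 higher and 8 not called, and 15 lower adjusted over the list alone (camera adjusted p = 1.75e-10, and adjusted p = 0.292 with an estimated correlation). Of 18 definitive endoderm genes 12 were lower, APOA1 (-8.13), SOX17 (-2.51) and FOXA2 (-2.75) among them, and 1 higher, with 14 lower and 2 higher adjusted over the list alone (camera adjusted p = 4.83e-07, and adjusted p = 0.412 with an estimated correlation). AFP, the fetal serum protein (-8.74 ± 2.61, adjusted p = 0.0313), was at 22820 TPM in fiaj1, 15910 in HUES8, 8546 in burb1 and 2059 in sojd3, and at 0.462 in cuhk2 and 0.132 in feec2. Of 18 endothelial and blood genes 7 were lower, with TIE1 (-2.69), KDR (-4.66) and PECAM1 (-2.97), and 13 adjusted over the list alone (camera adjusted p = 4.22e-08, and adjusted p = 0.412 with an estimated correlation). Of 17 amnion and surface ectoderm genes 6 were lower, with IGFBP3 (-5.83), GATA2 (-2.24), HAND1 (-5.26) and GATA3 (-2.74), and 9 adjusted over the list alone (camera adjusted p = 3.5e-07, and adjusted p = 0.265 with an estimated correlation). Of 20 core pluripotency genes 5 were lower, CDH1 (-5.55), L1TD1 (-3.87) and EPCAM (-4.67) among them, and SOX2 was the 1 higher, the same counts adjusted over the list alone (camera adjusted p = 6.48e-06, and adjusted p = 0.412 with an estimated correlation); LIN28A was at 711.3 TPM in sojd3, the organoid with the most POU5F1. Of 17 neural crest genes ETS1 (-4.53), ERBB3 (-3.88) and SNAI2 (-3.03) were lower and SOX9 (2.88) higher, with 3 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.0232, and adjusted p = 0.512 with an estimated correlation). In all 22 lists passed camera, 0 with an estimated correlation (adjusted p = 0.265 at the lowest) and 19 passed fry, and each list named here with called members kept its direction under both other scalings. The gene count was 3149 without hehd1, 3330 without kolf2, 3345 without fiaj1 and 3399 without H1, and 2329 without the sojd3, fiaj1 and burb1 organoids, a fit chosen after seeing the data.

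**Figure D3:**
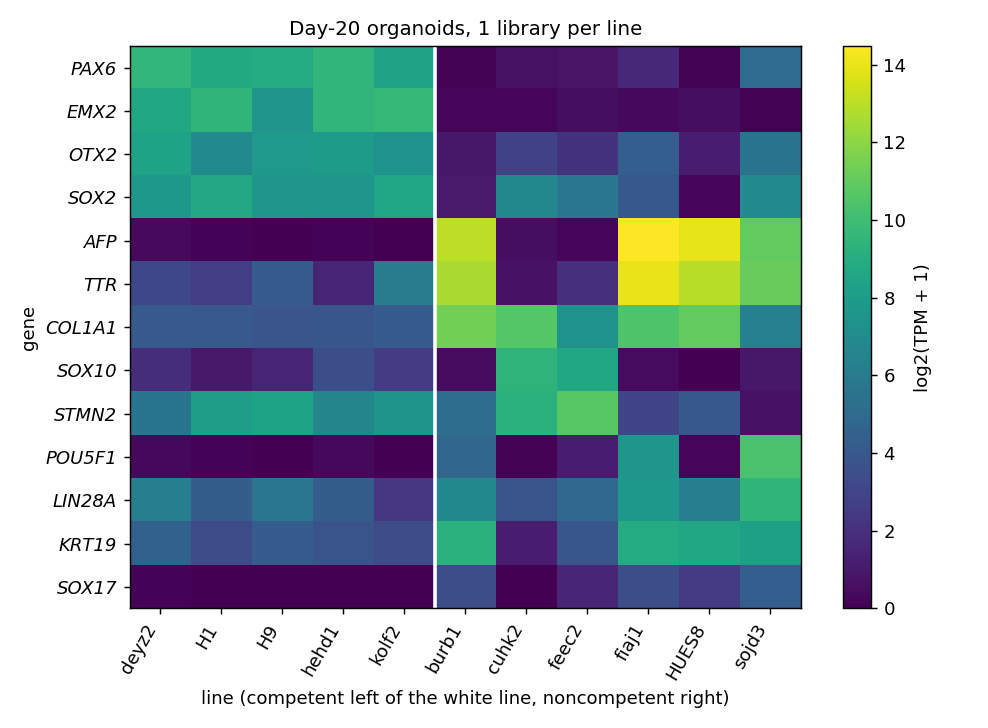
Heat map of log2(TPM + 1) for 13 genes in the 11 day-20 organoid libraries, 1 per line, with competent lines first. EMX2 was between 183.4 and 790.3 TPM in competent organoids and at most 0.4655 in noncompetent ones, while AFP was at 2059 TPM or more in burb1, fiaj1, HUES8 and sojd3, POU5F1 at 26.3 or more in burb1, fiaj1 and sojd3, and SOX10 at 397.7 or more in cuhk2 and feec2.

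Whether the untreated state goes with organoid identity across lines was asked with a score, the mean log2(TPM + 1) of a list. The organoid telencephalon score separated the groups, with a lowest competent value of 2.31 (H9) and a highest noncompetent value of 1.25 (sojd3), so no pooled correlation is given. Within the 6 noncompetent lines the posterior epiblast score of untreated cells and the telencephalon score of organoids had r = 0.106 (exact permutation p = 0.812, n = 6) and rho = 0.0857 (exact p = 0.919), 1 relation computed, so the adjusted p is also 0.812. Without cuhk2 and burb1, the lines farthest from the median, r was -0.627. With medians in place of means r was 0.915 (n = 6), with an exact permutation p under 0.05. The result turns on how the score is made, so no relation can be stated. No correlation was computed within the 5 competent lines.

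In sojd3 the CHR libraries of passages 37 and 38 stand in a table normalised separately, with 1 library each and no limma test. The sojd3 CHR libraries of the cell line table are called early here, though their passage is not given. SP8, GBX2 and other genes that CHR lowers were above their early CHR level in the late libraries. SP8 was at 77.7 ± 0.837 TPM untreated and 3.31 ± 0.485 in the early CHR libraries (n = 2 each), and at 18.1 and 23.4 TPM at passages 37 and 38. GBX2 was at 29.3 ± 6.73 and 1.48 ± 0.836 TPM, and at 24.0 and 27.0 in the late libraries. Taking the 246 genes that fell in both burb1 and fiaj1, the median change from untreated to early CHR in sojd3 was -1.15, and from early CHR to passage 37 and 38 it was 0.28 and 0.45, against 0.07 and 0.05 for all genes. For the 108 genes that rose in both lines the medians were 0.88, and then -0.05 and -0.27. Against untreated sojd3 the falling list stood at -0.90 and -0.67, and the rising list at 0.83 and 0.65, at passages 37 and 38.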

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

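The tests of a lower share of pluripotent cells, of both effects of the medium, of matched random lists and passage 38 for the late table and of a share of untreated cells in the late cultures were chosen after the result was seen.

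Single lines stood apart from the others of their group in 10 of 98 groups tested, where chance gives about 1 in 20. Levels are log2(TPM + 1), with the nearest other line in brackets. In untreated cells these were FAM71F1 in cuhk2 at 1.56 (1.23), ISLR2 in H9 at 0.423 (0.292), ZIC2 in HUES8 at 6.47 (7.02) and the posterior epiblast score of kolf2 at 0.77 (0.616). In organoids they were PAX6 in sojd3 at 5.03 (1.61), LHX5-AS1 in sojd3 at 2 (0.442), FEZF1-AS1 in cuhk2 at 1.94 (0.285), LAMB1 in cuhk2 at 9.41 (8.28), DMRT3 in H9 at 4.28 (5.97) and TBXT in deyz2 at 0.14, where the other competent organoids were listed at 0.

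PSMD5, MT1F, TBX1 and GBX2 were among 360 genes whose response to CHR differed between the 3 noncompetent lines and hehd1 by limma's test of the difference. Each of these named genes started from another level in hehd1 than in the noncompetent lines, which the test does not separate from the response. Singling out each of the 4 lines in turn makes too few splits for a share under 0.05, with 360 genes for hehd1 and 208 for the highest other line (1 of 4 gave as many).

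SP8, GBX2, UTF1 and ZIC1 led the difference between untreated competent and noncompetent lines. Chance was excluded at the 5% level: 2 of 100 splits of the lines, the real one included, gave as many genes, with 636 in the real split and 741 in the highest other. Embryonic or induced origin was argued against, since among the 8 induced lines 1 of 56 splits, the real one, gave 264 genes and the highest other 160. A lower share of pluripotent cells in 1 group was not decided. By limma's fry telencephalon genes were lower in competent lines (adjusted p = 0.0183, from 0.001109 before adjustment) while muscle genes were higher (adjusted p = 0.0183, from 0.00094). Neither list passed against other genes in camera with an estimated correlation (adjusted p = 0.385 each). The telencephalon list holds SP8, itself part of the difference. Opposite movement cannot exclude that each group held other cells of its own kind. A difference in the state of the lines, which the design names, stays open and may underlie it.

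SP8, ZIC1, UTF1 and TBX1 fell with CHR in the noncompetent lines. Chance was excluded at the level of libraries only, since 1 of 100 relabelings of libraries within lines, the real one, gave as many genes. The count was 3094, against 1944 for the highest other. These relabelings measure spread between libraries of these cultures and cannot speak of further lines. The count in hehd1 was 62 genes, against 898 in sojd3, the noncompetent line with the fewest. This argues against an effect of medium, coating and IWP2 of equal size in each line. It cannot decide on one that brings each line to the same level, since untreated hehd1 was already low in GBX2 (0.681 TPM) and ZIC1 (0.5465). Of the 52 genes that rose in hehd1, 21 also rose in burb1, 9 in fiaj1 and 10 in sojd3. Independent lists would share 1.348, 1.31 and 1.282. Of the same 52, 3, 13 and 8 fell in those lines. An effect of that culture that depends on the state of the line could give the same median shift of -1.283 in the genes lower in competent lines, and it cannot be told apart from CHR, since no noncompetent line was grown in that medium without CHR. CHR itself stays open in the same way.

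In the separate table of late CHR cultures of sojd3, SP8 was at 18.1 and 23.4 TPM at passages 37 and 38 against 3.31 in the early CHR libraries, and GBX2 at 24 and 27 against 1.48. A factor common to all genes of the late table was argued against, since from early CHR to passage 38 genes that fell with CHR had a median change of 0.4515 and genes that rose one of -0.2724, and the members kept for matching had 0.4793 and -0.2607, both outside 10000 random lists matched on expression. At passage 37 the 234 genes kept of those that fell had 0.286, above the random lists (-0.1203 to 0.1392), while the 102 kept of those that rose had -0.04143, in the low tail of theirs (percentile 1.29, range -0.1048 to 0.2131). A share of untreated cells in the late cultures would return each gene by about the same fraction. Over 52 genes the returned fraction had an interquartile range of 25.58 percentage points. These were genes that fell in burb1 and fiaj1, at 20 TPM or more in untreated sojd3 and far lower in its early CHR libraries. The same early libraries were the baseline of the fraction, so a gene low there by chance would appear to return. This was within 3 times the gap of 11.97 points between the passages, a limit too wide to decide the question. Single genes lay far from the median of 23.4%, CHCHD2 at -16.5% and GBX2 at 86.3%. GBX2 was at 24 and 27 TPM against 29.3 untreated, while ZIC1 was at 14.77 and 22.53 against 104.9. An equal share does not account for such genes. A gradual change in all cells and differences in processing gene by gene were not tested.

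Chance was excluded for the same 3 noncompetent lines before CHR against competent lines, where 1 of 56 splits, the real one, gave as many genes (473, highest other 190). It was excluded for organoids, where 2 of 100 splits gave as many (5154, highest other 5647). The competence assay was not analysed, so whether the groups were set from such organoids is unknown. If they were, a difference in organoid genes and scores would be given in advance. For PKIB, BEX1 and the other genes called across 4 lines it was not excluded, as 3 of 32 splits gave as many (21, highest other 49). After CHR the noncompetent lines had 0 genes against competent lines in limma, with 941 at an unadjusted p under 0.05, and the splits decide nothing there, as any of the 56 gives at least 0 (highest other 58).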

How the results depend on the processing

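Fits without mitochondrial genes, without the 2 libraries that stand apart and without 3 organoids were chosen after seeing the data. Depth is unknown, so precision rests on the spread between libraries. For named genes, 8995 values kept their direction and side of the threshold, 1105 lost the call, 36 gained it and 18 changed sign. For results that moved, the cause was not tested, except that a stricter filter tests fewer genes and left-out lines leave fewer samples.

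Untreated competent and noncompetent lines differed in 636 genes, and in 309 with no filter, 356 at a mean of at least 5 TPM, 264 in induced lines only, 1216 with the line as a random effect and 2624 with libraries as independent. Leaving out each line gave 340 to 1040 genes (340 without deyz2, 345 without H1, 350 without fiaj1, 354 without feec2, 394 without kolf2, 402 without sojd3, 1040 without cuhk2), and single replicates 329 (without replicate 1) and 502 (without replicate 2). The 21 genes across 4 lines became 0 with no filter, 0 under quantile normalization, 0 under median-of-ratios scaling, 41 with robust variance and 2269 over 16 libraries, and 0 to 627 with lines left out (0 without burb1, 1 without fiaj1, 627 without hehd1). At an unadjusted p under 0.05 limma gave 3229 genes. The 3094 genes of the noncompetent lines became 1790 at a mean of at least 5 TPM and 627 with paired line means, and 2284 to 2945 with libraries left out. In hehd1 62 became 156 with no filter, 29 at a mean of at least 5 TPM and 36 to 49 with libraries left out (36 without untreated replicate 1, 39 without CHR replicate 1, 39 without untreated replicate 2). The interaction count of 360 became 146 at a mean of at least 5 TPM and 177 to 375 with libraries left out (177 and 212 without hehd1 untreated replicates 1 and 2, 236 and 214 without its CHR replicates 1 and 2).

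Treated noncompetent against competent lines gave 0 genes in limma (941 at an unadjusted p under 0.05), 5 with no filter and 0 to 11 with lines left out (11 without sojd3). Untreated, the same lines gave 473, 137 with no filter, 254 at a mean of at least 5 TPM and 90 to 722 with lines left out (90 without fiaj1, 113 without sojd3, 231 without deyz2, 259 without H1, 263 without kolf2, 722 without H9). Organoids gave 5154 genes, 2329 without the sojd3, fiaj1 and burb1 organoids and 3149 to 7549 with lines left out (3149 without hehd1, 3330 without kolf2, 3345 without fiaj1, 3399 without H1). The lower shift list had a median of -1.82 at a pseudocount of 0.1. The score correlation was 0.9149 with list medians (exact permutation p = 0.00556). With an estimated correlation 0 lists passed camera in untreated lines, 5 in the noncompetent lines with CHR and 0 in organoids, and 5 passed fry in untreated lines.

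Without mitochondrial genes the counts were 664 for untreated lines, 3143 for noncompetent lines with CHR and 4996 for organoids. Without the libraries that stand apart, H9 untreated replicate 2 and sojd3 CHR replicate 2, they were 704 for untreated lines and 3490 for noncompetent lines with CHR.

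Replicate numbers of different lines showed no common tendency: over 105 pairs of 15 groups the median correlation of deviations was 0.0317, from -0.435 to 0.654. It was over 0.1 in 26.67% of pairs, and a median near 0 cannot exclude structure shared by some groups. With a replicate block the counts were 1163 for untreated lines with the line as a random effect, 2163 across 4 lines over 16 libraries, 3193 for the noncompetent lines, 63 for hehd1 and 362 for the interaction.

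Signs changed in genes that had missed the threshold. SOX2 in untreated lines was at -0.02162 under quantile normalization, -0.1104 without cuhk2, -0.01734 without H9, -0.05879 without hehd1 and -0.03422 in induced lines only, with 0.1891 the highest with a line left out. In hehd1 DNMT3B was at -0.09546 under quantile normalization, -0.04101 without mitochondrial genes, -0.1369 without CHR replicate 1 and -0.006414 without untreated replicate 2, with 0.1687 the highest with a library left out. NANOG in hehd1 ran from -0.2766 (without CHR replicate 1) to 1.132, OTX2 from -0.7462 to 0.03058 (without CHR replicate 1), and PAX6 from -0.1913 (without untreated replicate 1) to 0.45, with -0.01699 without CHR replicate 1. In treated noncompetent against competent lines OTX2 ran from -0.02487 (without deyz2) to 0.3819 and SOX2 from -0.2001 to 0.03418 (without hehd1), and with the same lines untreated DNMT3B from -0.31 to 0.05508 (without sojd3). DNMT3B in organoids ran from -0.92 to 0.08006 (without sojd3), and was at 0.7485 without the 3 organoids.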

Other observations

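The genes here were chosen after their values were seen. ZNF208, a zinc finger gene, rose with CHR in burb1 from 0.0478 to 19.7 TPM (4.30, limma adjusted p = 1.2e-12) and fell in fiaj1 from 10.6 to 0.00895 TPM (-3.52, adjusted p = 5.7e-11). NNAT, an imprinted gene expressed from the paternal copy, rose in burb1 from 0.0966 to 133.5 TPM (adjusted p = 3.15e-13) and fell in fiaj1 from 84.9 to 0.0904 TPM (adjusted p = 1.1e-12), while in sojd3 it was at 115.9 TPM before and 70.7 after (adjusted p = 0.105). MEG3, an imprinted noncoding RNA, rose in burb1 from 0.0441 to 103.8 TPM (6.65, adjusted p = 5.3e-13), and in fiaj1 its change was 0.16 (adjusted p = 0.818). Among untreated lines MEG3 was at 53.7 TPM in kolf2 and at most 0.674 in the others.

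CHCHD2 was near 0 in untreated feec2 (0.240 ± 0.340 TPM, n = 2) and in fiaj1 after CHR (0.128 TPM), with 135.3 TPM in untreated fiaj1. PSMD5 was at 0.163 TPM in untreated hehd1 and 25.8 after CHR. In organoids the glial and neural crest gene SOX10 was at 686.9 TPM in cuhk2 and 397.7 in feec2, and the neuronal gene STMN2 at 605.6 and 1706. TTR, a thyroxine carrier of liver and choroid plexus, was at 16490 TPM in fiaj1, 7738 in HUES8, 6278 in burb1 and 2221 in sojd3 (1 library per line).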
